A study of Mus musculus with 12 samples.

How the data were processed

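Hearts of 12 male mice were profiled, 6 HKII+/- and 6 HKII+/+. Per the labels' protocols, RNA was purified with QIAzol and an RNeasy kit, mRNA was captured by its poly(A) tail, and libraries were sequenced on an Illumina instrument as single-end reads of 100 nt. The submitters' processing notes name STAR 2.4.0 and featureCounts 1.4.4 and the genome builds mm10 and GRCm38, which are the same assembly. The deposited values are whole-number counts per gene symbol, one table per library, with no normalisation by the authors. The strand setting and the annotation release are not given in the sources used here. All 12 tables list the same 24061 symbols in the same order. Libraries are treated as separate animals on the strength of their separate titles, and if any shared an animal the p-values would measure less than the spread between animals.

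Counts summed to 17263209 to 51556592 per library, and this depth sets the precision of low genes. Replicates of a genotype were checked for duplicate deposits with a chi-square over genes with at least 20 counts in a pair, and the lowest value per degree of freedom was 7.03, far above the value of sampling noise. Replicate numbers do not recur between the genotypes, so no pairing was tested.

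Groups came from the genotype in the sample titles. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest) on the counts, with TMM factors, filterByExpr (minimum count 10) and Benjamini-Hochberg adjustment at 0.05, over all 12 libraries with no covariate. Intervals are 95% from the fitted standard error. CPM are counts scaled by the TMM-adjusted library total. Lists of genes for pathways and cell types were fixed before the data were examined and tested with camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 and adjustment over the 48 lists with at least 3 measured members (29 pathway and 19 cell type lists), and again with an estimated correlation and with fry. Hk2 and list means were compared by exact two-sided permutation tests over all splits of the libraries. Neighbours were genes within 20 Mb of Hk2 and were compared with other genes by Fisher's exact test at unadjusted p below 0.01. Library similarity used Pearson correlations of log2 CPM and principal components of 500 genes. R was version 4.3.3.

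Named genes followed a rule fixed beforehand: measured hexokinases, called genes and then those with the smallest p at an average log2 CPM of at least 0 up to 20 genes, the 3 members with the smallest p of each called list, 2 members of 3 further lists, and Nppa, Nppb, Myh7, Acta1 and Myh6. 1 gene named by the rule is not reported here. Myl7, the genes near Hk2 other than Hk2 and Kbtbd12, and the genes given in the closing section outside this rule were chosen after their values were seen.

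Coordinates and transcript GC content came from the GENCODE vM21 annotation of GRCm38. Of the symbols, 22709 matched directly, 914 through an older symbol, 42 matched several genes and 396 none. A GC value, from the longest transcript, was available for 99.1% of tested genes.

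The fits were first tested on simulated counts with 100 genes changed by 1.5-fold and 100 by 2-fold. A gene list was raised as well, and counts were drawn independently for each gene, without differences that genes of a library share. With the means, sizes and dispersions of 12 libraries (13883 genes), 2% and 13% were recovered and 0 unchanged genes were called. With those of the 10 unmarked libraries (14033 genes), 77% and 87% were recovered and 5 unchanged genes were called.

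Alternatives fixed before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma voom with and without sample quality weights, a surrogate variable from sva 3.50.0, another threshold, other windows, and leaving out each library or both marked ones. A GC correction, an atrial marker covariate and several combinations without the marked libraries were added after seeing the data.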

Results

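RNA was measured in 12 heart samples of male C57BL/6J mice aged 2 to 4 months and kept on chow. Of these, 6 were heterozygous for hexokinase II (HKII+/-) and 6 were wild type (HKII+/+). Hexokinase II, encoded by Hk2, phosphorylates glucose in the opening step of glycolysis and can bind the outer membrane of mitochondria. The design compared the 2 genotypes, to ask how the heart transcriptome differs when the gene dose of Hk2 is lowered. The deposited gene counts summed to between 17263209 (HKII+/+ replicate 18) and 51556592 (HKII+/- replicate 22) per library. Of 24061 listed gene symbols, 14107 passed the filter on low counts. The submitters marked HKII+/- replicate 11 and HKII+/+ replicate 13 as potential outliers, and values are given with both (n = 6 per genotype) and without them (n = 5 per genotype).

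Hk2 was lower in 5 of the 6 HKII+/- libraries than in any HKII+/+ library. Hk2 (ENSMUSG00000000628.10) lies on chromosome 6 from 82725025 to 82774454 on the minus strand of GRCm38 and is annotated as protein coding. In the HKII+/+ libraries it measured 471 (replicate 14), 485.5 (21), 522 (17), 524.1 (18), 542.5 (15) and 652.6 (13) CPM. In the HKII+/- libraries it measured 255.7 (replicate 20), 266.9 (16), 272.6 (12), 312.5 (19), 354 (22) and 568.2 (11) CPM. In TMM-scaled CPM the library labelled HKII+/- replicate 11 therefore lay inside the HKII+/+ range, against its label. It enters every comparison below that uses all 12 libraries. Its TMM factor was 0.787, against 0.992 to 1.09 in the unmarked libraries. As a share of total counts, without that factor, its Hk2 (13360 of 29924460) lay below every HKII+/+ library (lowest 10661 of 21594153, replicate 21). By both measures Hk2 in this library lay above the other HKII+/- libraries. The mean was 338.3 ± 118 CPM in HKII+/- and 532.9 ± 64.4 CPM in HKII+/+ hearts (SD, n = 6 each). The log2 fold change was -0.66 (SE 0.20, 95% interval -1.08 to -0.23), with an exact two-sided permutation p of 0.013 over 924 splits. In edgeR's quasi-likelihood test Hk2 had an unadjusted p of 0.00542 and a Benjamini-Hochberg adjusted p of 1, so it did not pass across all genes. With the same 12 libraries it passed with sample quality weights in limma voom (log2 fold change -0.88, SE 0.07, adjusted p = 7.66e-05) and with 1 surrogate variable in edgeR (-0.74, SE 0.09, adjusted p = 0.0194).

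Without the 2 marked libraries Hk2 fell to 57.5% of the HKII+/+ level (95% interval 50.3% to 65.7%). The means were then 307.9 ± 42.3 and 535.7 ± 31.5 CPM (SD, n = 5 each), the log2 fold change was -0.80 (SE 0.09) and the edgeR adjusted p was 0.0165. The exact permutation p was 0.00794, the smallest that 252 splits can give. This call was lost when HKII+/- replicate 12, 16, 19 or 20 or HKII+/+ replicate 15, 17 or 18 was left out as well, with adjusted p between 0.0522 and 0.0951. It held without HKII+/+ replicate 14 (0.0367), HKII+/+ replicate 21 (0.0307) or HKII+/- replicate 22 (0.00106).

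**Figure D1:**
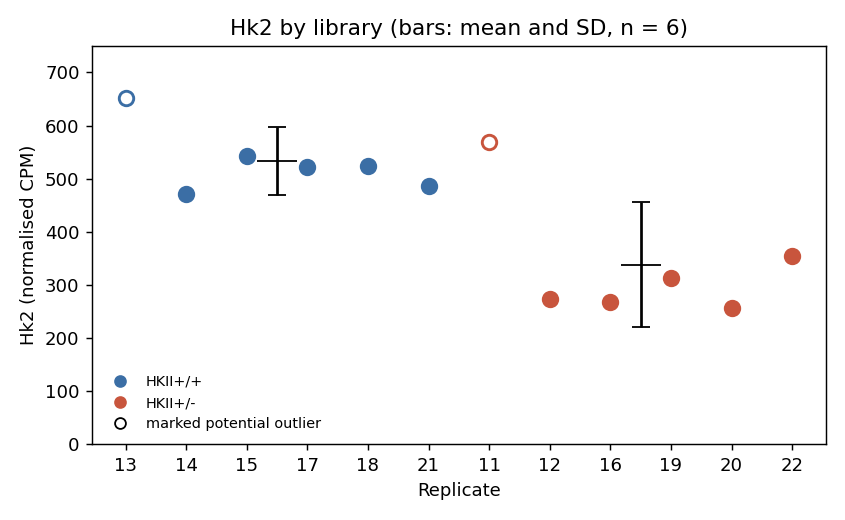
Hk2 in each library, in TMM-normalised CPM on the y axis and replicate number on the x axis; open circles are the libraries marked as potential outliers, and bars show the mean and SD of 6 libraries per genotype. The 5 unmarked HKII+/- libraries lie between 255.7 and 354 CPM, below every HKII+/+ library, while the library labelled HKII+/- replicate 11 lies at 568.2 CPM.

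Hk1 and Hk3 did not pass the test. Hk1, the main hexokinase of most tissues, measured 241.8 ± 24.5 CPM in HKII+/- and 257.4 ± 52.4 CPM in HKII+/+ hearts (SD, n = 6 each), with a log2 fold change of -0.09 (95% interval -0.39 to 0.20). Without the marked libraries it was 0.02 (95% interval -0.15 to 0.20). Hk3 was low in both genotypes, at 2.29 ± 2.18 and 2.12 ± 1.33 CPM, and its log2 fold change was 0.12 (SE 0.50) with all libraries and -0.17 (SE 0.17) without the marked ones. Taken as a list, the hexokinase family fell by camera (adjusted p = 0.00307), or adjusted p = 0.687 with an estimated correlation. The list includes Hk2 itself, so its fall is not a result separate from that of Hk2. Of its 4 measured members 1 (Hk2) passed when adjusted over the list alone against 0 over all genes tested. The list was no longer called without HKII+/+ replicate 13 (adjusted p = 0.783), HKII+/- replicate 16 (0.054) or HKII+/- replicate 20 (0.056).

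In edgeR no gene passed an adjusted p of 0.05 between the genotypes with all 12 libraries. In this quasi-likelihood test 37 genes (0.262% of those tested) had an unadjusted p below 0.05, of which 24 were higher and 13 lower in HKII+/- hearts. DESeq2 called 0 genes (115 at unadjusted p below 0.05) and limma voom called 0 (33). Sample quality weights, which nearly leave out the marked libraries, gave 2 called genes, Hk2 and Kbtbd12, with 671 at unadjusted p below 0.05. With 1 surrogate variable 1 gene was called, Hk2, with 375. Without the marked libraries 1 gene of 14139 passed, Hk2, and 396 genes (2.8%) were at unadjusted p below 0.05, 214 higher and 182 lower. Both edgeR shares lie below the fraction of 0.05 that chance would give on average. Genes are not independent, so these shares do not show that the p-values run large. In other splits of the 10 unmarked libraries into groups of equal size, 159 to 3019 genes were at unadjusted p below 0.05. On the 10 unmarked libraries DESeq2 called 3 (Hk2, Antxr2 and Kbtbd12) and quality weights 1 (Hk2). The median standard error of a log2 fold change was 0.25 with all libraries and 0.09 without the marked ones. In data simulated from these libraries, 13% of genes changed by 2-fold were recovered with 12 libraries and 87% with 10. Many genes were changed at once there and counts were drawn independently for each gene. These shares therefore do not give the power to find few changed genes.

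The genes with the smallest p at an average log2 CPM of 0 or more were named by a rule set before the data were examined, and none passed the adjusted test in edgeR with all 12 libraries. Of them Kbtbd12 passed with sample quality weights (log2 fold change 0.835, adjusted p = 0.0361). In DESeq2 without the marked libraries Kbtbd12 (0.77, adjusted p = 0.0206) and Antxr2 (0.29, adjusted p = 0.0233) passed. Lower values in HKII+/- hearts were seen for Fam109b (log2 fold change -0.62), Gm7120 (-0.79), Fam83g (-0.50), Ifitm10 (-0.52), the pseudogene Pisd-ps1 (-0.25) and Scn4b, a sodium channel beta subunit (-0.31, SE 0.11). Pisd-ps1 may share reads with its parent gene, so its value is uncertain. Higher values were seen for Antxr2 (0.31, SE 0.11), Kbtbd12 (0.64, SE 0.25), Tmem253 (0.44), Sdcbp2 (0.40), Trim62 (0.40), Tmem198 (0.50), Upk1a (0.53), Ism1 (0.74) and Wt1, a mesothelial transcription factor (0.42). Tmem253 and Sdcbp2 were higher in 6 of 6 HKII+/- libraries than in any HKII+/+ library, at an exact permutation p of 0.00216 each before any correction for the number of genes. Cyp2f2 and Wfdc2, genes of airway epithelium, had log2 fold changes of 5.63 and 3.88 that came from the library labelled HKII+/- replicate 11 (190.6 and 29.4 CPM). Without the marked libraries the values were -0.34 and -0.12. Ism1, at 5.997 CPM in the same library, was at 0.38 without it and 0.36 without the marked libraries.

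The usual transcripts of cardiac stress did not pass the test. Nppa, which encodes atrial natriuretic peptide, measured 4194 ± 4624 CPM in HKII+/- and 3037 ± 1112 CPM in HKII+/+ hearts (SD, n = 6 each), with log2 fold changes of 0.47 with all libraries and -0.17 without the marked ones. It was lowest in HKII+/- replicates 19 (267.8 CPM) and 22 (430.9), the libraries lowest in atrial markers, and highest in HKII+/- replicate 11 (12950). Its log2 fold change was 0.71 without 19, 0.72 without 22 and -0.31 without 11, so the value depends on which of these libraries enter. Nppb, for B-type natriuretic peptide, had log2 fold changes of -0.09 (SE 0.23) and 0.07 (SE 0.17). The myosin heavy chains Myh7 and Myh6 were at 0.07 (SE 0.38) and -0.003 (SE 0.42) with all libraries, and the sign for Myh6 turned with upper-quartile scaling (0.002). Acta1, the skeletal actin of the fetal heart, measured 341.8 ± 141 and 588.8 ± 395 CPM (log2 fold change -0.78, SE 0.42). HKII+/+ replicate 21 held 1360 CPM, and without it the log2 fold change was -0.35. Its adjusted p was 1 in edgeR.

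Lists of mitochondrial energy metabolism and the calcium handling list were slightly lower by camera with all 12 libraries. The pyruvate dehydrogenase and TCA cycle list fell by camera, with 25 of 26 members lower and an adjusted p of 0.000184 (adjusted p = 0.687 with an estimated correlation). Its members with the smallest p, Sdhb (log2 fold change -0.13), Suclg1 (-0.11) and Pdhx (-0.12), did not pass singly. Fatty acid uptake and oxidation fell by camera, with 21 of 23 members lower (adjusted p = 0.00622, and adjusted p = 0.687 with an estimated correlation), and held Hadha at -0.10, Hadh at -0.12 and Echs1 at -0.12. Oxidative phosphorylation complex I fell, with 31 of 36 lower (adjusted p = 0.00565, and adjusted p = 0.687 with an estimated correlation), and held Ndufb9 at -0.15, Ndufs4 at -0.16 and Ndufa7 at -0.12. Complexes III to V fell, with 29 of 37 lower (adjusted p = 0.0336, and adjusted p = 0.755 with an estimated correlation), and held Cycs at -0.13, Cox8b at -0.17 and Cyc1 at 0.33. Calcium handling fell, with 15 of 16 lower (adjusted p = 0.044, and adjusted p = 0.755 with an estimated correlation), and held Asph at -0.11, Calm3 at -0.05 and the calsequestrin Casq2 at -0.11. In these lists 0 members passed when adjusted over the list alone or over all genes tested (edgeR, with 0 of them at unadjusted p below 0.05). As list means per library none differed between the genotypes. The exact permutation p was 0.576 (TCA cycle), 0.587 (fatty acid oxidation), 0.398 (complex I), 0.665 (complexes III to V) and 0.366 (calcium handling).

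Whether these lists were called changed with the libraries and covariates used. In the library labelled HKII+/- replicate 11, whose TMM-scaled Hk2 level went against its label, the TCA cycle list averaged 8.31 log2 CPM, against 8.97 to 9.29 in the other HKII+/- libraries. Without that library the adjusted p was 0.996 (TCA cycle), 0.854 (fatty acid oxidation, other direction), 0.662 (complex I), 0.736 (complexes III to V, other direction) and 0.579 (calcium handling, other direction). Without HKII+/+ replicate 13 it was 0.17, 0.338, 0.939, 0.939 and 0.282 in the same order. The call for fatty acid oxidation was also lost without HKII+/- replicate 12 (adjusted p = 0.077) or 16 (0.0558), and that for complex I without 12 (0.208) or 16 (0.0669). Complexes III to V lost it without HKII+/- replicate 12 (0.464), 16 (0.174) or 20 (0.0609) or HKII+/+ replicate 18 (0.185). Calcium handling lost it without HKII+/- replicate 16 (0.054) or HKII+/+ replicate 15 (0.0717), 17 (0.0592), 18 (0.068) or 21 (0.21). Without both marked libraries camera called none of the 5 lists, and complex I and complexes III to V pointed the other way (adjusted p = 0.855 and 0.53). In the same 10 libraries with the mean of the atrial markers as a covariate, 4 of the 5 were lower and called: the TCA cycle (adjusted p = 1.29e-10), fatty acid oxidation (8.84e-08), complex I (8.84e-08) and complexes III to V (1.67e-05). With an estimated correlation these were at adjusted p = 0.13, 0.495, 0.635 and 0.669. The same 4 lists were lower and called when HKII+/- replicates 19 and 22, lowest in atrial markers, were left out along with the marked libraries (8.29e-13, 4.86e-09, 1.23e-09 and 2.68e-08, and adjusted p = 0.268, 0.535, 0.535 and 0.535 with an estimated correlation). That left HKII+/- replicates 12, 16 and 20. Neither fit was particular to these lists, as camera called 17 of 48 lists with the covariate and 20 of 49 without replicates 19 and 22. Both sets included glycolysis and lactate, PPAR-alpha target genes, outer membrane channels, antioxidant defence, the sarcomere, cytosolic ribosomal proteins and ventricular cardiomyocytes. Leaving out replicate 19 alone with the marked libraries gave 0.0379 for the TCA cycle and 0.0487 for fatty acid oxidation, and leaving out replicate 22 gave 5.7e-05, 0.0105 and, for complex I, 0.034. With an estimated correlation no list was called in either of these (lowest adjusted p = 0.883). With sample quality weights the TCA cycle alone of the 5 was called, at 0.0119 with 12 libraries and 0.00563 with 10, and with an estimated correlation at adjusted p = 0.988 and 0.994. Calcium handling also lost its call with the GC trend removed (0.0813).

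Of the other pathway lists, 6 were higher and called with all 12 libraries. Immediate early genes, which respond within minutes to stimuli, rose by camera with 22 of 25 members higher (median log2 fold change 0.24, adjusted p = 1.87e-06, and adjusted p = 0.687 with an estimated correlation), among them Fosb (0.62, SE 0.46), Atf3 (0.44, SE 0.41) and Klf4 (0.21, SE 0.21). The heat shock response rose, with 13 of 20 members higher (adjusted p = 0.011, and adjusted p = 0.755 with an estimated correlation), and held Hspa1a at 1.47 (SE 0.59), Hspa1b at 1.68 (SE 0.75) and the co-chaperone Dnajb1 at 0.58 (SE 0.26). Hspa1a and Hspa1b are near-identical copies, so the division of reads between them is uncertain. The interferon response rose, with 22 of 24 higher (adjusted p = 0.00165, and adjusted p = 0.687 with an estimated correlation), and held Igtp at 0.76, Oas1a at 0.33 and Oas2 at 0.20. The unfolded protein and integrated stress response rose, with 17 of 21 higher (adjusted p = 0.00365, and adjusted p = 0.687 with an estimated correlation), and held Dnajc3 at 0.17, Phgdh at 1.15 and Chac1 at -0.42. Extracellular matrix and fibrosis rose, with 23 of 29 higher (adjusted p = 0.0421, and adjusted p = 0.795 with an estimated correlation), and held Ctgf at 0.87, Eln at 1.22 and Col3a1 at 1.20. Cell cycle genes rose, with 12 of 18 higher (adjusted p = 0.0258, and adjusted p = 0.687 with an estimated correlation), and held Birc5 at 0.61, E2f1 at 0.37 and Cdk1 at 0.39. In these lists 0 members passed in edgeR when adjusted over the list alone or over all genes tested, and 4 were at unadjusted p below 0.05. For the list means per library the exact permutation p was 0.273 (immediate early genes), 0.452 (heat shock) and 0.537 (interferon). It was 0.318 for the unfolded protein, 0.833 for the extracellular matrix and 0.53 for the cell cycle list.

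Of these lists, immediate early genes alone were called without each of the 12 libraries in turn. With an estimated correlation no list was called in any of these fits (lowest adjusted p = 0.0667). HKII+/- replicate 12 held the most Hspa1a, Hspa1b, Dnajb1, Fosb and Atf3 of all libraries (53.52, 59.3, 56.91, 6.235 and 38.11 CPM). Without it their log2 fold changes were 0.84, 0.99, 0.38, 0.42 and 0.18, and Klf4 was at 0.14 without HKII+/- replicate 22. The library labelled HKII+/- replicate 11 held Eln at 2108 and Col3a1 at 6294 CPM, the highest values of its genotype, and Ctgf at 989.5 CPM. The log2 fold change of Ctgf was 0.18 without it and 0.25 without the marked libraries, and Eln and Col3a1 were at -0.95 and -0.89 without it. Phgdh and Oas1a, at 19.44 and 4.721 CPM in the same library, were at -0.32 and 0.06 without it, and Igtp, at 90.5 CPM in HKII+/- replicate 19, was at -0.09 without that library. Without replicate 11 the adjusted p was 0.579 for the unfolded protein, 0.216 for the interferon and 0.203 for the cell cycle list, and extracellular matrix pointed the other way (0.0474). Without HKII+/+ replicate 13 it was 0.0914, 0.282, 0.783 and 0.281 in the same order, and 0.341 for heat shock. The heat shock call was also lost without HKII+/- replicate 12 (0.791) or 22 (0.547) or HKII+/+ replicate 14 (0.0739), the unfolded protein call without HKII+/- replicate 12 (0.208) and the interferon call without HKII+/- replicate 19 (0.737). The cell cycle call was lost without HKII+/- replicate 19 (0.193) or HKII+/+ replicate 17 (0.0604) or 21 (0.121), and that of extracellular matrix without HKII+/- replicate 16 (0.0573) or HKII+/+ replicate 17 (0.122), 18 (0.253) or 21 (0.134). With all 12 libraries and the atrial covariate the call was lost for heat shock (0.463), interferon (0.165) and cell cycle (0.142). With sample quality weights it was lost for the unfolded protein (0.229), interferon (0.705) and cell cycle lists (0.736), and extracellular matrix pointed the other way (0.705). Extracellular matrix lost it with the GC trend removed (0.0853) or a surrogate variable (0.258), and cell cycle with a surrogate variable (0.0833) or a mean CPM of at least 1 (0.503). Without both marked libraries it was lost for the unfolded protein (0.104), interferon (0.152) and cell cycle lists (0.56), and extracellular matrix pointed the other way (0.515).

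In all, 12 of 48 lists were called by camera, 6 higher and 6 lower, and 0 with an estimated correlation or by fry. The count was 6 without HKII+/- replicate 11, 1 without HKII+/+ replicate 13, 19 without HKII+/+ replicate 14 and 7 without HKII+/- replicate 16, and 0 in each of these with an estimated correlation. Without both marked libraries 4 lists were called: immediate early genes (higher, adjusted p = 1.45e-06), heat shock response (higher, 4.18e-05), atrial cardiomyocyte (lower, 0.021) and hexokinase family (lower, 0.0241), which includes Hk2 itself. The lowest was then adjusted p = 0.967 with an estimated correlation. The call for the hexokinase family was lost without HKII+/+ replicate 15 (0.0626) or 21 (0.104) or HKII+/- replicate 16 (0.0711) or 20 (0.0773) as well, and that for atrial markers without HKII+/+ replicate 14 or 15 or HKII+/- replicate 19 or 22. The count of 4 became 14 without HKII+/- replicate 12, 9 without HKII+/+ replicate 18 or HKII+/- replicate 20, and 8 without HKII+/- replicate 22. As list means per library, immediate early genes averaged 4.86 ± 0.20 log2 CPM in HKII+/- and 4.55 ± 0.50 in HKII+/+ hearts (SD, n = 5 each, exact permutation p = 0.254). The heat shock list averaged 7.53 ± 0.36 and 7.24 ± 0.17 (exact permutation p = 0.151), and HKII+/- replicate 12 stood highest at 8.0.

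Other pathway lists were not called in the main fit with all 12 libraries. With 1 surrogate variable camera called antioxidant defence, the sarcomere and cytosolic ribosomal proteins. With the atrial covariate it called antioxidant defence and mitochondrial fission, fusion and mitophagy. With 1 library left out it called antioxidant defence without HKII+/+ replicate 14, 15 or 17 or HKII+/- replicate 19 or 22. The hypertrophy and fetal gene programme was called without HKII+/+ replicate 14 or 17, and the sarcomere without 14 or 15. Mitochondrial fission, fusion and mitophagy was called without HKII+/+ replicate 14 or HKII+/- replicate 22, and glycolysis and lactate without 22. The inflammatory list was called without HKII+/+ replicate 15 and the glucocorticoid response without 21. With an estimated correlation no list was called in these fits (lowest adjusted p = 0.3, 0.0626 and 0.202). The values that follow are from the main fit. Glycolysis and lactate had 7 of 21 members higher (adjusted p = 0.301), with the lactate transporter Slc16a3 at 0.66 (SE 0.45), which was -0.07 without HKII+/- replicate 11 (16.67 CPM), and the glucose transporter Slc2a1 at -0.13 (SE 0.10). Outer membrane channels, permeability transition and cell death had 8 of 23 higher (adjusted p = 0.332), with Casp9 at -0.12 and the adenine nucleotide carrier Slc25a4 at -0.15. Adjusted p was 0.647 for glycogen metabolism, 0.546 for the pentose phosphate and hexosamine pathways, 0.479 for PPAR-alpha target genes and 0.143 for mitochondrial fission, fusion and mitophagy. It was 0.839 for mitochondrial biogenesis regulators, 0.833 for the hypoxia response, 0.0626 for antioxidant defence and 0.086 for the hypertrophy and fetal gene programme. For the sarcomere it was 0.301, for autophagy 0.332, for insulin, Akt and mTOR signalling 0.428 and for the circadian clock 0.489. Inflammatory cytokines and acute phase and the glucocorticoid response were both at 0.467, as were the cytosolic ribosomal proteins. Camera pointed lower while the mean log2 fold change was above 0 for glycogen metabolism, PPAR-alpha target genes, the hypoxia response and ribosomal proteins, whose medians were below 0. For the circadian clock camera pointed higher and the median was -0.015.

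Markers of atrial muscle and fat differed widely between libraries. Myl7, the atrial myosin light chain, had 24 counts in HKII+/- replicate 22 and 394 in HKII+/- replicate 19, against 3985 to 28320 in the others. The atrial cardiomyocyte list averaged 1.64 and 3.42 log2 CPM in these libraries and 5.99 to 8.26 in the rest. The white adipocyte list was lowest in the same libraries, at 1.0 and 1.45 log2 CPM, followed by HKII+/+ replicate 13 at 1.81, and highest in HKII+/- replicate 11 at 6.13. Between genotypes the atrial list means were 5.94 ± 2.72 and 6.73 ± 0.54 (SD, n = 6 each, exact permutation p = 0.494). For this list the median log2 fold change was 0.28 while camera pointed lower (adjusted p = 0.0736). The atrial list was called without HKII+/- replicate 11, 12, 16 or 20 or HKII+/+ replicate 17 or 21. With an estimated correlation it was called in none of these.

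**Figure D2:**
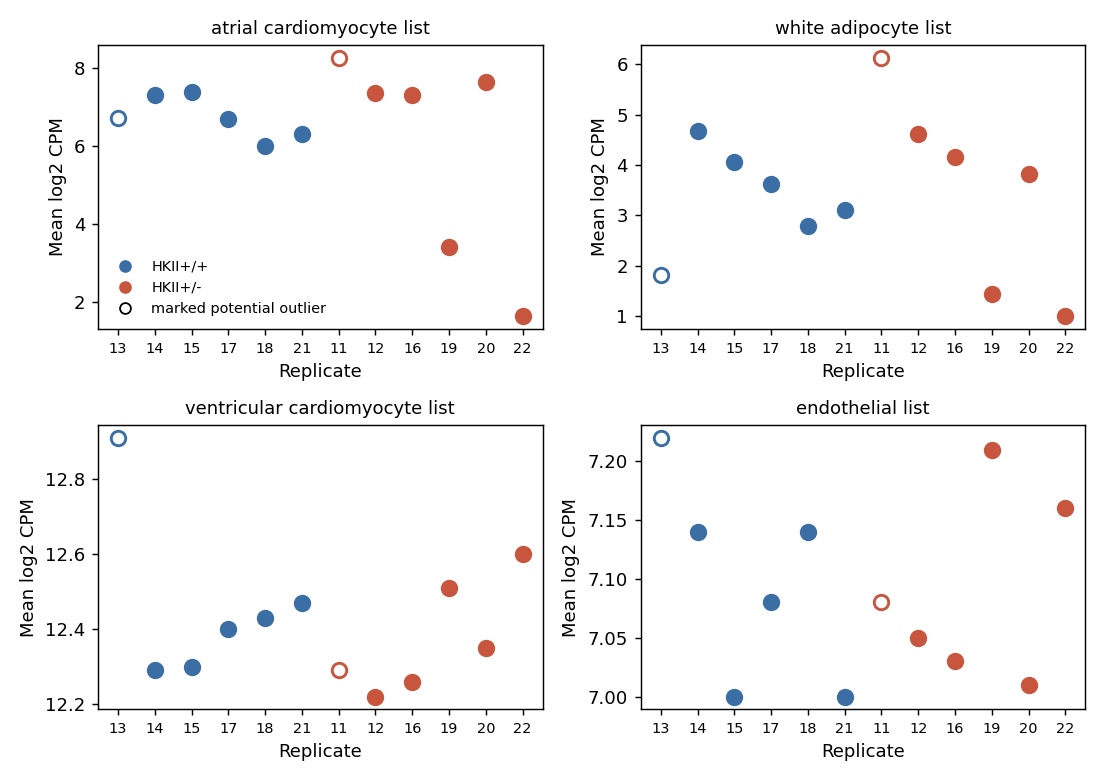
Mean log2 CPM of 4 marker lists in each library, with replicate numbers on the x axis and open circles for the libraries marked as potential outliers. HKII+/- replicates 19 and 22 lie lowest for the atrial list, at 3.42 and 1.64, and lowest for the white adipocyte list.

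Of the other cell type lists none was called in the main fit with all 12 libraries. With 1 surrogate variable camera called ventricular cardiomyocytes. With the atrial covariate it called the conduction system, white adipocytes, Schwann cells and neurons, and mesothelium. With 1 library left out camera called the conduction system without HKII+/+ replicate 14, 15 or 17 or HKII+/- replicate 22. B cells were called without HKII+/+ replicate 14, 17 or 21. White adipocytes were called without HKII+/+ replicate 14 or HKII+/- replicate 19 or 22, and Schwann cells and neurons without 19 or 22. Mesothelium was called without replicate 22, ventricular cardiomyocytes without 14, skeletal muscle without 11 and erythroid cells without 17. With an estimated correlation no list was called in any of these fits (lowest adjusted p = 0.0626). The adjusted p given next are from the main fit. Adjusted p was 0.265 for ventricular cardiomyocytes, 0.0626 for the conduction system, 0.677 for endothelial, 0.769 for lymphatic endothelial and 0.952 for endocardial markers. It was 0.722 for fibroblasts, 0.647 for smooth muscle and for pericytes, 0.931 for macrophages, 0.0733 for B cells and 0.461 for erythroid cells. For white adipocytes it was 0.467, for brown adipocytes 0.904, for skeletal muscle 0.25, for Schwann cells and neurons 0.156, for mesothelium 0.434, for cartilage and bone 0.555 and for Y chromosome genes 0.559. Camera pointed lower while median and mean log2 fold changes were above 0 for endocardial, brown adipocyte, skeletal muscle and cartilage and bone markers, and for macrophages the mean alone was above 0. Lists with fewer than 3 measured members were not tested: the mitochondrial DNA encoded genes, neutrophils, T cells and thymus, lung epithelium, liver, oesophagus and trachea epithelium, and X inactivation. With a mean CPM of at least 1 as the filter, lung epithelium was tested and called higher (adjusted p = 0.00378, and adjusted p = 0.651 with an estimated correlation). Its member Cyp2f2 had 4481 counts in the library labelled HKII+/- replicate 11 and at most 54 elsewhere. This filter was not run without that library. Under the same filter atrial cardiomyocyte and antioxidant defence were called lower (0.0453 and 0.0467, and adjusted p = 0.725 and 0.651 with an estimated correlation).

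The 2 marked libraries stood apart from the others. Their mean Pearson correlation across genes with the other libraries of their genotype was 0.826 (replicate 11) and 0.907 (replicate 13), against 0.946 to 0.976 for the rest. Myh6, the adult myosin heavy chain, took 9.89% and 9.95% of their counts, against 3.72% to 4.78%. The first principal component of the 500 most variable genes held 63.8% of the variance, and both libraries lay at its low end (-74.2 and -46.0, the others from 9.2 to 15.1). Gene deviations in both correlated with transcript GC content, at r = 0.62 and 0.63 across genes, which are not independent replicates, against -0.30 to 0.13 in the others.

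**Figure D3:**
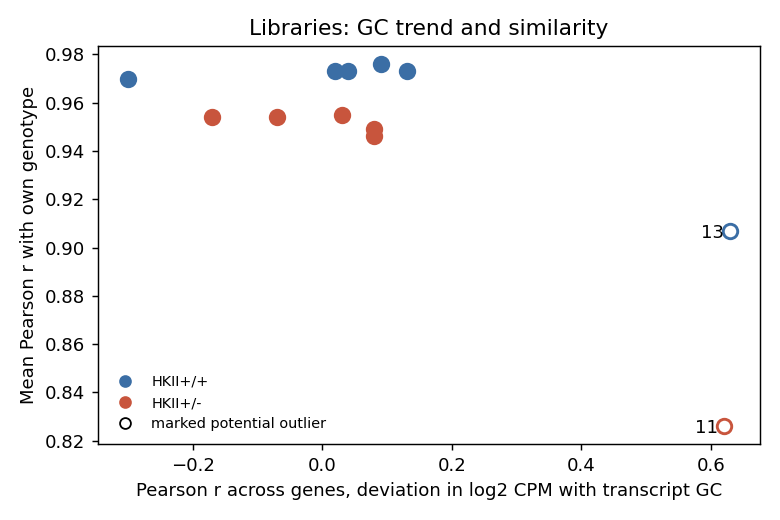
Mean Pearson correlation of each library with its own genotype (y axis) against the correlation, across genes, of its deviation in log2 CPM with transcript GC content (x axis). Replicates 11 and 13 lie apart at r = 0.62 and 0.63, and the other 10 libraries lie between -0.30 and 0.13.

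Genes around Hk2 were compared with the rest of the genome, since a targeted allele can carry neighbouring chromosome from the strain of the embryonic stem cells. With all 12 libraries 0 genes within 20 Mb of Hk2 passed the adjusted threshold in edgeR, and 1 of 186 was at unadjusted p below 0.01 (Lbx2, log2 fold change -0.98, SE 0.27) against 2 of 13792 elsewhere (two-sided Fisher's exact p = 0.0394). The exact p was 0.113 without HKII+/+ replicate 13, 0.0524 without HKII+/+ replicate 15 and 0.0774 without HKII+/- replicate 22, and the count was 2 without HKII+/- replicate 11 and without HKII+/+ replicate 21. The exact p was also 0.0522 with upper-quartile factors, 0.0648 with DESeq2 size factors, limma voom or the GC trend removed, 0.102 with the atrial covariate, 0.135 with DESeq2, 0.2 with no filter, 1 with a mean CPM of at least 1 and 0.0796 in a window of 40 Mb. With sample quality weights, which nearly leave out the marked libraries, 12 of 186 were at unadjusted p below 0.01 (Fisher's exact p = 7.84e-08). Kbtbd12 among them passed the adjusted threshold. With 1 surrogate variable 3 were at unadjusted p below 0.01 (Fisher's exact p = 0.016). Without the marked libraries 6 of 185 neighbours (3.24%) were at unadjusted p below 0.01, against 47 of 13823 other genes (0.34%), with an odds ratio of 9.82 and a Fisher's exact p of 6.71e-05. Of these, 3 were higher in HKII+/- hearts: the membrane repair gene Dysf (84008590 to 84211060, log2 fold change 0.30, SE 0.07), Kbtbd12 (88545114 to 88637950, 0.78, SE 0.16) and Mgll, for monoacylglycerol lipase (88724412 to 88828360, 0.30, SE 0.09). Lower values were seen for the long noncoding RNA 2310069B03Rik (82877864 to 82881853, -0.78, SE 0.22), Lbx2 (83086367 to 83088243, -0.89, SE 0.25) and Abtb1 (88835914 to 88841984, -0.24, SE 0.07). Of these, 2310069B03Rik and Lbx2 were scarce, at 0.52 and 0.47 CPM in HKII+/- against 0.94 and 0.89 CPM in HKII+/+ hearts. Their average log2 CPM of -0.34 and -0.43 lay below the 0 asked of genes named by p. None of the 6 passed the adjusted test in edgeR (adjusted p of 1.0), while DESeq2 on the same libraries called Kbtbd12 (adjusted p = 0.0206), and all lie on the distal side of Hk2, 0.103 to 6.06 Mb away. The count without the marked libraries was 10 without HKII+/- replicate 16 as well and 13 without HKII+/+ replicate 21, and in the latter Kbtbd12 passed with an edgeR adjusted p of 0.0307. Strand use in the counting was not given in the sources used here, so reads of overlapping antisense genes could not be separated.

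**Figure D4:**
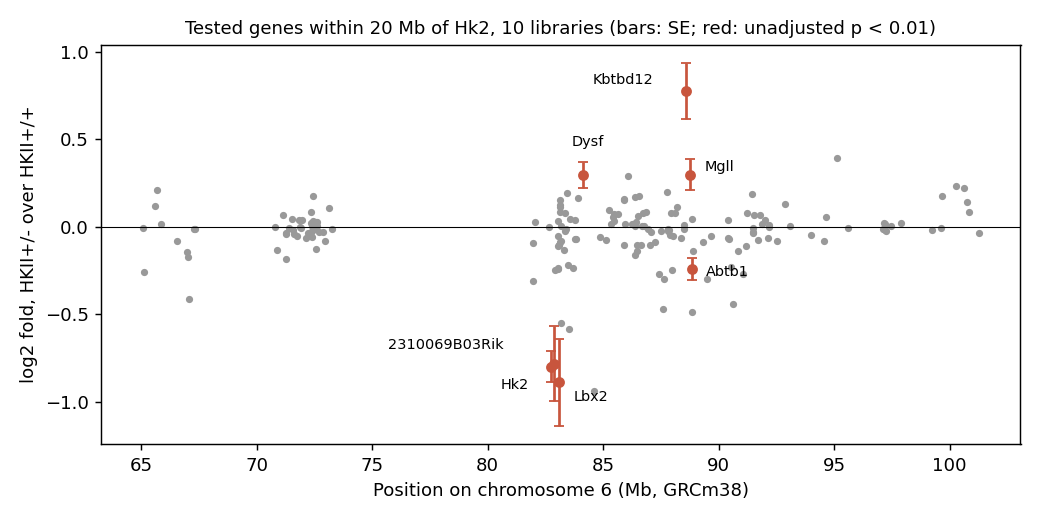
Log2 fold change (HKII+/- over HKII+/+, y axis) of the tested genes within 20 Mb of Hk2 by position on chromosome 6 (x axis, Mb, GRCm38), from 10 libraries; red points with SE bars are at unadjusted p below 0.01. Hk2 and 6 neighbours are red, and Kbtbd12 at 0.78 lies farthest above 0.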

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

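The tests of the GC trend, of other tissue in replicate 13, and of Hk2 by library were prompted by values already seen, and the tests of the corrected similarity, the genotype label and the corrected Hk2 level were set before their results were seen. A value far from the other 5 of its genotype, by Dixon's 95% critical value, was found in 66 of 232 groups of 6, of which 32 were in HKII+/- replicate 11, 28 in HKII+/+ replicate 13 and 6 in other libraries. Chance flags about 1 in 20 groups, or 11.6 here.

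Library measures of both marked libraries stood apart. Their TMM factors were 0.787 (replicate 11) and 0.76 (replicate 13), Myh6 took 9.89% and 9.95% of counts, and mean correlations were 0.826 and 0.907. The GC correlation of 0.62 stood apart in replicate 11.

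Genes high in the library labelled HKII+/- replicate 11 were Hk2 (568.2 CPM), Hk3 (6.72), Cyp2f2 (190.6), Wfdc2 (29.35), Ism1 (5.997), Ctgf (989.5), Eln (2108), Col3a1 (6294), Phgdh (19.44), Oas1a (4.721), Slc16a3 (16.67), Nppa (12950), Myh7 (2463) and Myh6 (125900). Asph (164.8 CPM) and Casq2 (454.6) were low there. In HKII+/+ replicate 13 the high genes were Hk1 (359 CPM), Hk3 (4.787), Hspa1a (15.48), Hspa1b (19.67), Echs1 (583.7), Ndufs4 (251.9), Ndufa7 (144.7), Cox8b (457.5), Eln (488.4), Col3a1 (1757), Slc16a3 (5.771), Slc25a4 (8442), Myh7 (2360) and Myh6 (130900).

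List means in log2 CPM stood apart in replicate 11 for the hexokinase family (6.5), extracellular matrix and fibrosis (7.67) and cytosolic ribosomal proteins (7.47), which were high. Low there were glycogen metabolism (5.86), the TCA cycle (8.31), fatty acid oxidation (8.02), mitochondrial fission, fusion and mitophagy (6.03), mitochondrial biogenesis regulators (5.13), antioxidant defence (5.89), insulin, Akt and mTOR signalling (5.47), lymphatic endothelial markers (3.11) and Y chromosome genes (2.19). In replicate 13 the hexokinase family (6.79), glycolysis and lactate (8.23), sarcomere (12.24), cytosolic ribosomal proteins (7.64) and ventricular cardiomyocyte (12.91) lists were high. Glycogen metabolism (6.13), the TCA cycle (8.93), mitochondrial biogenesis regulators (5.5), calcium handling (8.53), lymphatic endothelial markers (3.1) and Y chromosome genes (3.13) were low there.

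Outside these libraries, Gm7120 was high in HKII+/- replicate 16 (8.609 CPM), Dnajc3 in HKII+/- replicate 12 (110.8), Igtp and Birc5 in HKII+/- replicate 19 (90.5 and 1.647), and Kbtbd12 and Acta1 in HKII+/+ replicate 21 (31.42 and 1360).

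The separation of replicates 11 and 13 may in part reflect a loss of AT-rich transcripts, since the lower of their correlations with GC content was 0.62 and the largest absolute value elsewhere was 0.30. The trend as removed here does not account for the whole difference: after its removal the lower mean correlation with unmarked libraries of the same genotype was 0.878, against 0.826 before, and still below the lowest of the others at 0.979. Tissue from outside the ventricle cannot be told apart for replicate 13: 2 of 17 cell type lists lay above the other HKII+/+ libraries (2.83 expected by chance), a single tissue would raise few lists, and Col3a1 and Eln were high. In replicate 11, 11 of 17 lay above the other HKII+/- libraries, Cyp2f2 had 4481 counts (at most 54 elsewhere), and Scgb1a1, an abundant transcript of airway club cells, had 491. Genotype does not set them apart, as each genotype holds 1 of the 2 libraries.

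Whether the GC trend explains the Hk2 level of the library labelled HKII+/- replicate 11 cannot be told from its removal. Hk2 was still 516 CPM there after the removal, and the lowest HKII+/+ library was at 465.7. In HKII+/+ replicate 13, with a like GC trend, Hk2 also stayed high, at 603.4 CPM. The unmarked HKII+/+ libraries lay at 465.7 to 540.8 CPM, so the removal may be incomplete. A wrong genotype label cannot be told apart from other sources: only 2 genes besides Hk2 differed at unadjusted p below 0.001 in the other libraries, and 1 of them lay nearer the HKII+/+ mean in this library. The TMM scaling also bears on the place of this library: as a share of total counts its Hk2 lay below every HKII+/+ library. Hk2 from other tissue in this library stays open and was not tested.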

How the results depend on the processing

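Sign changes are listed for every named gene and called list, although most concern values near 0 that never passed a test. Over 2967 comparisons of a result with an alternative, 2427 kept their direction and their side of the threshold, 258 changed direction (187 of them on leaving out a library) and 4 of these were past the threshold, all gene lists. Hk2 was lower in all 38 alternatives (log2 fold change -0.94 to -0.57, adjusted p 1.11e-13 to 1) and passed in 10. Alternatives with the GC correction, the atrial covariate or both marked libraries left out together with another choice were chosen after seeing the data. The cause was not tested except where fewer libraries entered. The median SE of a log2 fold change was 0.249 with all libraries and 0.213 for genes averaging at least 10 CPM, and 0.089 and 0.07 without the marked libraries.

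Leaving out both marked libraries gave 1 called gene, 6 neighbours and 4 lists, and Hk2 at -0.799. Hk1 was then 0.023, Hk3 -0.173, Cyp2f2 -0.338, Wfdc2 -0.119, Echs1 0.003, Ndufa7 0.018, Cox8b 0.039, Eln -0.365, Col3a1 -0.103, Phgdh -0.116, Slc25a4 0.022, Nppa -0.17, Nppb 0.069 and Myh6 0.032, and adjusted p of the reversed lists was 0.855 (complex I), 0.53 (complexes III to V) and 0.515 (extracellular matrix). DESeq2 on these libraries called 3 genes (Hk2, Antxr2 and Kbtbd12), 7 neighbours and 1 neighbour past the adjusted threshold, with Hk2 -0.796, Hk1 0.026, Hk3 -0.172, Cyp2f2 -0.245, Wfdc2 -0.098, Echs1 0.005, Ndufa7 0.021, Cox8b 0.043, Eln -0.362, Col3a1 -0.102, Phgdh -0.111, Slc25a4 0.025, Nppa -0.171, Nppb 0.071 and Myh6 0.035. Quality weights on these libraries gave 1 gene, 10 neighbours and 4 lists, with Hk2 -0.885, Hk3 -0.229, Cyp2f2 -0.714, Eln -0.326, Col3a1 -0.086, Phgdh -0.153, Nppa -0.378, Nppb 0.051 and extracellular matrix reversed (adjusted p 0.571). With the atrial covariate there were 1 gene and 7 neighbours, with Hk2 -0.892, Hk3 -0.206, Cyp2f2 -0.091, Eln -0.101, Nppb 0.1 and Myh7 -0.008. Also leaving out HKII+/- replicates 19 and 22 gave 1 gene, 6 neighbours and 20 lists (17 with the atrial covariate in 10 libraries), with Hk2 -0.939, Hk3 -0.249, Eln -0.007, Igtp -0.269, Nppb 0.16, Myh7 -0.032 and the interferon list reversed (adjusted p 0.219).

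With all 12 libraries, quality weights, which nearly leave out replicates 11 and 13, gave 2 genes (Hk2 and Kbtbd12), 12 neighbours, 1 of them past the adjusted threshold, and 4 lists, with Hk2 -0.884, Hk3 -0.232, Cyp2f2 -0.694, Eln -0.331, Col3a1 -0.09, Phgdh -0.153, Nppa -0.39, Nppb 0.046 and extracellular matrix reversed (adjusted p 0.705). A surrogate variable gave 1 gene and 3 neighbours, with Hk2 -0.743, Hk3 -0.174, Eln -0.147 and Myh7 -0.022. Under limma voom Hk3 was -0.049, Nppa -0.441 and Myh6 0.002. Myh6 was 0.002 with upper-quartile factors, 0.018 with a mean CPM of at least 1 (where 0 neighbours were at p below 0.01) and 0.046 with the atrial covariate, and Hk3 was -0.027 with the GC trend removed. An estimated correlation and fry both left 0 lists. An estimated correlation also left 0 with the atrial covariate (lowest adjusted p 0.0626) and with quality weights (0.902, extracellular matrix reversed at 0.988), and, without the marked libraries, with that covariate (0.13), with quality weights (0.994, extracellular matrix reversed at 0.994) and without HKII+/- replicates 19 and 22 (0.268, interferon response reversed at 0.853). Over genes with a mean CPM of at least 10 the mean correlations of replicates 11 and 13 were 0.658 and 0.793, and over 2000 genes the first component held 74.3%.

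Leaving out each library in turn, with or without the marked ones (the latter chosen after seeing the data), gave 0 to 2 genes, 1 to 13 neighbours, 0 to 1 neighbours past the adjusted threshold, 1 to 19 lists and Hk2 from -0.876 to -0.571. Log2 fold changes ranged for Hk1 from -0.142 to 0.054, Hk3 -0.566 to 0.548, Cyp2f2 -0.747 to 6.065, Wfdc2 -0.227 to 4.129, Sdhb -0.186 to 0.027, Suclg1 -0.159 to 0.021, Hadha -0.155 to 0.026, Hadh -0.169 to 0.008 and Echs1 -0.167 to 0.06. They ranged for Ndufb9 from -0.206 to 0.011, Ndufa7 -0.173 to 0.072, Cox8b -0.221 to 0.1, Calm3 -0.074 to 0.022, Casq2 -0.17 to 0.035, Eln -0.946 to 1.833, Col3a1 -0.89 to 2.005, Phgdh -0.413 to 1.388 and Igtp -0.093 to 1.013. For Slc16a3 the range was -0.071 to 0.873, Slc25a4 -0.198 to 0.06, Nppa -0.475 to 0.723, Nppb -0.228 to 0.176, Myh7 -0.318 to 0.471 and Myh6 -0.447 to 0.488. Named genes that kept their direction, with a log2 fold change moved by a factor of more than 1.5, were Scn4b -0.348 to -0.204, Wt1 0.258 to 0.492, Kbtbd12 0.536 to 0.961, Hspa1a 0.806 to 2.051, Hspa1b 0.826 to 2.465, Dnajb1 0.381 to 0.895, Ism1 0.207 to 0.891, Tmem198 0.31 to 0.585, Upk1a 0.39 to 0.85, Pdhx -0.177 to -0.015, Ndufs4 -0.201 to -0.009, Cyc1 0.233 to 0.56, Cycs -0.169 to -0.002 and Asph -0.151 to -0.001. The others were Ctgf 0.017 to 1.067, Dnajc3 0.05 to 0.205, Chac1 -0.759 to -0.289, Fosb 0.303 to 0.997, Atf3 0.18 to 0.972, Klf4 0.141 to 0.365, Oas1a 0.047 to 0.429, Oas2 0.132 to 0.307, Birc5 0.348 to 0.685, E2f1 0.218 to 0.465, Cdk1 0.225 to 0.566, Slc2a1 -0.171 to -0.071, Casp9 -0.166 to -0.052 and Acta1 -0.96 to -0.309. Adjusted p ranged for the TCA cycle from 1.52e-07 to 0.996, fatty acid oxidation 0.000103 to 0.976, complex I 3.43e-05 to 0.939, complexes III to V 0.000282 to 0.948, calcium handling 0.00674 to 0.979, extracellular matrix 0.00185 to 0.979 and interferon response 7.84e-07 to 0.884. Lists past the threshold in the other direction were extracellular matrix without HKII+/- replicate 11 (adjusted p 0.0474) and, without both marked libraries, complex I (0.00444) and complexes III to V (0.000282) without HKII+/- replicate 12 and complexes III to V without HKII+/+ replicate 18 (0.0191). With an estimated correlation no list was called in these fits (lowest adjusted p 0.886, 0.848 and 0.959).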

Other observations

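The tests of atrial tissue and of the stem cell strain were chosen after their results were seen, and the tests of windows and of other splits were set before. A B cell marker list averaged 2.35 log2 CPM in HKII+/+ replicate 15, against -0.40 to 0.99 in the other libraries. The atrial chamber genes Myl7 and Sln were at 0.469 and 0.0782 CPM in HKII+/- replicate 22 and at 19.1 and 5.47 CPM in HKII+/- replicate 19. Ucp1, the uncoupling protein of brown fat, had 0 counts in both and in HKII+/+ replicate 13, and 2969 in HKII+/+ replicate 14. Among the 10 unmarked libraries the first principal component of 500 genes held 71.9% of the variance, with HKII+/- replicates 19 and 22 at 32.7 and 43.5 and the others from -17.3 to 3.8. Lypla1 had 127 and 153 counts in replicates 11 and 13 and 1768 to 4837 in the others.

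Other splits of the libraries into groups of equal size were drawn, 100 of the 462 possible with 12 libraries and 100 of the 126 possible with 10, the real split included. With 12 libraries the real split gave 0 called genes, which every one of the 100 splits reached, and the highest of the others gave 1. Without the marked libraries the real split gave 1 gene, as many or more came in 5 of 100, and the highest other gave 386, so chance is not excluded for the count. That split set replicates 12, 14, 15, 16 and 20 against 17, 18, 19, 21 and 22. On the first principal component of the 10 unmarked libraries the former lay at -17.3 to -14.5 and the latter at -5.1 to 43.5. The 386 genes thus follow the main difference between the samples, with HKII+/- replicates 19 and 22 at its far end. For called lists, 30 of 100 splits gave at least the real 12 (highest other 31), and without the marked libraries 99 of 100 gave at least the real 4 (highest other 30). A camera p as small came in 16 of 100 splits for immediate early genes (real 3.02e-08, smallest other 1.92e-20) and in 21 of 100 for heat shock (real 1.74e-06, smallest other 3.51e-15). Chance is excluded for none of these list results.

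The excess of small p near Hk2 is a pattern a biologist may wish to follow up. Such a count was rare elsewhere: of windows of the same width around 13626 tested genes, 112 (0.822%) held as many such genes, and the highest held 6. These windows overlap one another, and genes that lie close together count separately. The share is therefore not a probability, and position by chance cannot be decided from it. The difference in atrial tissue as the whole cause is argued against in the 10 unmarked libraries. There all 6 neighbours stayed with the atrial covariate (7 in all, Fisher's exact p = 0.00117, odds ratio 4.69 against 9.82 without it). Without HKII+/- replicates 19 and 22 as well, 6 neighbours were at unadjusted p below 0.01 (Fisher's exact p = 0.0184, odds ratio 3.01). Dysf and Mgll were no longer among them. With all 12 libraries atrial tissue stays open as a cause (0.102, 1 neighbour). A chance division of the libraries stays open: 8 of 100 splits gave at least the real 6 neighbours, and the highest other gave 16. By the rule set beforehand this share keeps chance as an explanation. The comparison has a limit that was not part of that rule: it counts neighbours without setting them against other genes. It therefore cannot decide on the excess. The other splits with as many neighbours had 1043 to 3019 genes at unadjusted p below 0.05 in all, against 396 in the real split. Chromosome of the embryonic stem cell strain cannot be told apart from an effect of the Hk2 allele itself, because gene counts hold no sequence, and the farthest of these genes lies 6.06 Mb away.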
